A study of Mus musculus with 4 samples.

How the data were processed

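Single-nucleus RNA sequencing was read from 4 libraries of mouse left ventricular apex tissue, 2 from control hearts and 2 from a model of heart failure with preserved ejection fraction (HFpEF model), named here by group and replicate. Per the labels' protocols, nuclei were loaded on a droplet instrument with 3′ chemistry and unique molecular identifiers (UMIs). The labels do not give the treatment that makes the model, the strain, the sex, the time of day of collection, or whether each library comes from 1 animal. P-values here therefore measure only the spread between these libraries.

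The deposited values are raw UMI counts per gene and barcode, 1 matrix per library, with 33696 genes each; every value is a whole number. Per the submitters' processing notes, the authors used Cell Ranger 9.0.0 and Seurat 5.2.1, and the notes do not say which step each served. No cell type table was used here, so classes were rebuilt here. Gene symbols and identifiers are those the files pair. The counts use the mouse build GRCm39, and the annotation at hand is of an older build, so no coordinates are given. Gene spans from that older annotation served in 1 test only, as a property of a gene, for 96.4% to 98.9% of the genes tested in a class.

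Nuclei were kept with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs. The limits on UMIs and genes removed 0 barcodes. The mitochondrial limit removed 30.8% and 40.9% of barcodes in the control libraries against 2.08% and 1.51% in the HFpEF model libraries. Scrublet, as run by scanpy with an expected rate of 0.1, then called 4.68%, 7.71%, 13.5% and 16.0% of the remaining nuclei doublets (control 1, control 2, HFpEF model 1, HFpEF model 2), and these were removed. The labels state 10000 nuclei, against 20036 to 32548 barcodes per library in the files and 16568 to 20851 nuclei kept.

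All nuclei that passed the filters, called doublets included, were clustered on 2000 variable genes chosen by library, 30 principal components, 15 neighbours and Leiden resolution 1.0, with no batch integration. Clusters were named with the doublets present, and the doublets were dropped before counts were summed. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used. A cluster was called "X-like" from fixed markers of 17 cell types if its mean marker score was at least 0.5 and led the next type by at least 0.4, with at least 3 markers detected. At most 0.5 of its barcodes could be called doublets, and no other type could have more markers among its 10 leading genes. These limits, but not the markers, were set after the data were seen. Macrophage-like and pericyte-like clusters whose cardiomyocyte marker level was over 0.5 of that in cardiomyocyte-like clusters were set apart as background-laden, also after the data were seen. Other classes were not held to this limit. The level was 39040 CPM (explained below) in T or NK-like, 40045 in B-like and 35435 in Schwann-like nuclei. In cardiomyocyte-like clusters it was 58143 to 75375 CPM. T or NK-like and B-like nuclei therefore lay above the limit and Schwann-like nuclei about at it, and none were set apart. The unnamed cluster nearest to cardiomyocytes had a low median UMI count (1667) and Lars2, Hbb-bs, Fth1, Uqcr11 and Cox4i1 among its leading genes. It served as the profile of free RNA, and its nuclei are called free-RNA-like.

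Counts were summed per library and class, since nuclei are not replicates. Sums were compared between groups with edgeR 4.0.16 under R 4.3.3, by the quasi-likelihood test with TMM scaling, its own filter on low counts and Benjamini-Hochberg adjustment over the genes tested. The threshold is an adjusted p under 0.05. The standard error (SE) of a log2 fold change is the fold change divided by the square root of the F statistic, an approximation. Levels are given as CPM, the counts of a class scaled to one total per library. Every fold change is HFpEF model over control. Classes with at least 30 nuclei in each library were tested (11 classes); B-like nuclei were not, with 29 nuclei in 1 library.

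Gene lists (36, written before the data were examined) were tested by limma 3.58.1, with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a class. Camera with an estimated correlation and fry served as alternatives. The correlation is then estimated from only 4 libraries, and whether camera so run can find a changed list was not tested. Shares of classes were compared by edgeR's quasi-likelihood test on numbers of nuclei and by a two-sided exact permutation test over 6 orders of the libraries, whose smallest p is 0.333. Intervals on shares are 95% Clopper-Pearson intervals and cover counting error only. Differences between 2 classes were tested by an interaction term in edgeR with the library as a block.

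The genes named per main class are the 8 higher and 8 lower with the largest fold change among those past the threshold, with mean CPM of at least 20, both libraries of one group above both of the other, a named gene model, and, outside cardiomyocytes, a CPM in cardiomyocyte-like nuclei of at most 5 times that in the class. From each list, up to 4 members with the smallest adjusted p were added. For the other classes the rule takes 4 and 4. Genes named outside the rule are said to be so where they appear. The tests of the main results, the lists, the markers and this rule were fixed before the data were examined.

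The procedure was tested on simulated counts with 200 changed genes per class. Of genes changed 2-fold it recovered 72.5% in macrophage-like nuclei (10532 genes tested), 66.2% in cardiomyocyte-like (17597), 71.2% in fibroblast-like (14592), 71.4% in vascular endothelial-like (12255) and 65.8% in pericyte-like nuclei (10932). Of genes changed 1.5-fold it recovered 11.5%, 34.8%, 37.0%, 31.7% and 17.2%, in that order. The simulated spread of each gene lay on the fitted trend, with no spread of its own, and fewer genes changed than were called in the data. Recovery in the data may therefore be lower. Alternatives covered the scaling, the tool (DESeq2 1.42.0), the filters on genes and nuclei, doublets, clustering, purity of classes, background RNA, the replicate number as a block, and each library left out. Alternatives added after the data were seen are a 10% mitochondrial limit, background-laden clusters included, the free RNA profile subtracted, and shares of named nuclei alone. Under the 10% limit Scrublet called 0% of control 1, so the 10% of its nuclei with the highest score were removed instead.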

Results

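The study asked how hypertensive stress changes macrophages in hearts of a non-obese mouse model of heart failure with preserved ejection fraction, in which the ventricle stiffens while its pumping function is kept. Nuclei from the left ventricular apex were profiled in 2 control libraries and 2 HFpEF model libraries. The control libraries held 102976454 and 104460961 UMIs over 29162 and 32548 barcodes, with a median of 2278 and 2022 UMIs per barcode. The HFpEF model libraries held 84982316 and 87442374 UMIs over 24621 and 20036 barcodes, with medians of 2265 and 2622. Before any filter, a median of 3.49% and 4.18% of UMIs per barcode were mitochondrial in the control libraries, against 1.70% and 1.27% in the HFpEF model libraries. After filtering, 19241, 17765, 20851 and 16568 nuclei were kept (control 1, control 2, HFpEF model 1 and HFpEF model 2), with median UMI counts of 3034, 3172, 2190 and 2539.

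The kept nuclei fell into 12 named classes, led by cardiomyocyte-like nuclei (34.8% and 38.1% of kept nuclei in the control libraries, 23.0% and 33.3% in the HFpEF model libraries) and fibroblast-like nuclei (17.6% and 16.9% against 17.2% and 13.6%). Macrophage-like nuclei, the immune cells the study is about, made up 3.28% (95% interval 3.04% to 3.55%) and 4.24% (3.95% to 4.55%) of control nuclei and 5.68% (5.37% to 6.01%) and 3.46% (3.19% to 3.75%) of HFpEF model nuclei. The log2 ratio of their shares was 0.28 (SE 0.34; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.661; two-sided exact permutation p = 0.667), and without HFpEF model 1 it was -0.12. With the background-laden macrophage nuclei added, an alternative chosen after the data were seen, the log2 ratio was 0.66 (edgeR adjusted p = 0.177). Neither passed. Pericyte-like nuclei, which wrap capillaries, made up 6.19% and 6.23% against 3.29% and 3.50% (log2 ratio -0.87, edgeR adjusted p = 0.0860, and -0.28, 0.593, with background-laden pericyte nuclei added). Vascular endothelial-like nuclei made up 10.8% and 9.01% against 6.42% and 5.37% (log2 ratio -0.75, edgeR adjusted p = 0.114). Of the 15 shares tested by edgeR, 0 passed after adjustment and 6 had an unadjusted p under 0.05. The exact permutation test cannot go below 0.333 here.

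Several clusters stayed outside the classes through limits set after the data were seen. Unnamed nuclei made up 14.0% and 9.69% of control nuclei and 22.3% and 24.6% of HFpEF model nuclei. Among them, an unnamed cluster nearest to vascular endothelial cells held 2.30% and 0.777% against 10.8% and 9.93%. The free-RNA-like cluster, nearest to cardiomyocytes, held 4.63% and 2.21% against 9.05% and 12.9%. Unnamed clusters nearest to fibroblasts held 6.71% and 6.25% against 2.33% and 1.65%, and the unnamed cluster nearest to pericytes held 0.333% and 0.338% against 0.106% and 0.0423%. Background-laden macrophage nuclei made up 2.46% and 1.61% against 5.07% and 4.10%, and background-laden pericyte nuclei 2.14% and 1.23% against 2.88% and 3.30%. Shares of the named classes therefore rest on which clusters were named, and on a mitochondrial limit that removed 30.8% and 40.9% of control barcodes against 2.08% and 1.51% of HFpEF model barcodes.

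**Figure D1:**
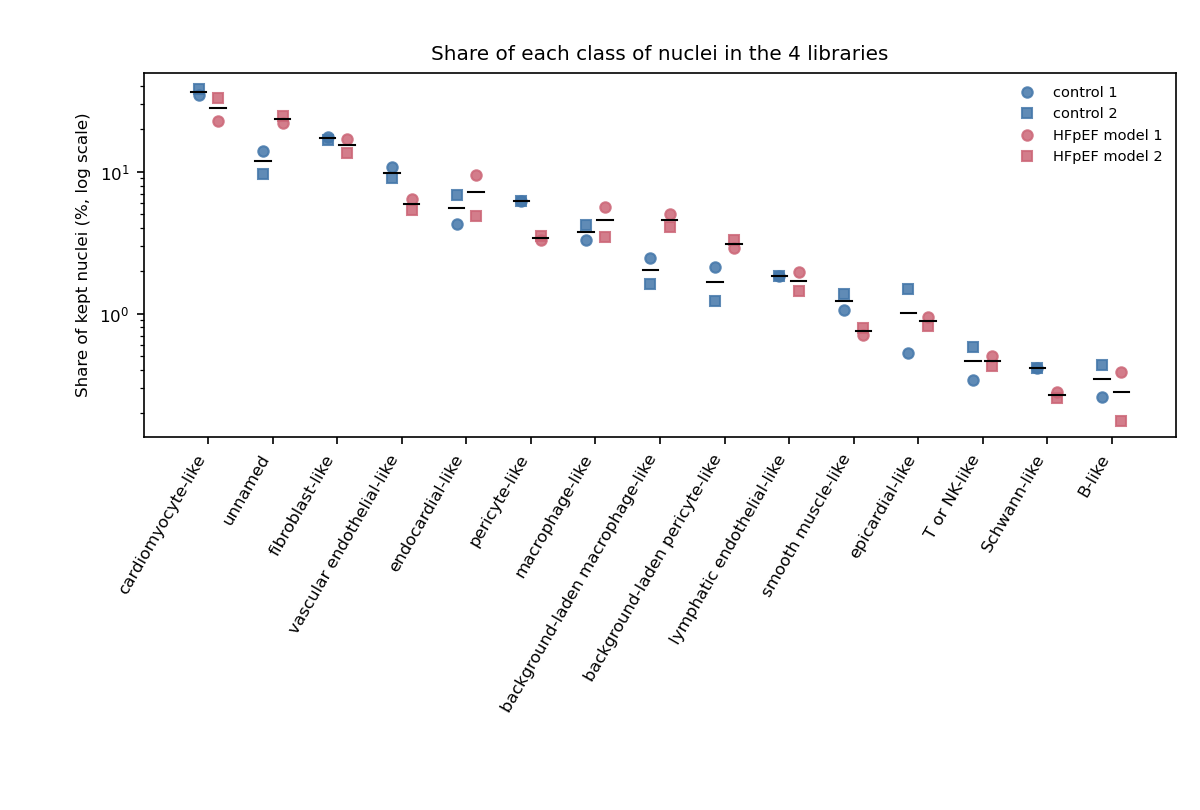
Share of each class among kept nuclei (vertical axis, percent on a log scale) for each class (horizontal axis); circles and squares are replicates 1 and 2, blue is control, red is the HFpEF model, and black bars are group means. The macrophage-like shares of the groups overlap (3.28% and 4.24% against 5.68% and 3.46%), while the pericyte-like shares do not (6.19% and 6.23% against 3.29% and 3.50%).

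In macrophage-like nuclei Ms4a4a (ENSMUSG00000101389), a membrane protein of macrophages, rose from 41.4 ± 4.40 to 514 ± 35.1 CPM (SD, n = 2 per group, log2 fold change 3.65, SE 0.15, edgeR adjusted p = 6.96e-06). Clec4d, a C-type lectin that senses microbial lipids, rose from 2.88 to 45.1 CPM (3.96), and Mmp12, the macrophage elastase, from 6.62 to 58.7 CPM (3.06, edgeR adjusted p = 0.00646). Timd4 (ENSMUSG00000055546), a receptor by which resident macrophages bind dying cells, fell from 123 ± 24.5 to 20.9 ± 2.64 CPM (SD, n = 2 per group, log2 fold change -2.52, SE 0.20, edgeR adjusted p = 0.000191). Cmah (ENSMUSG00000016756), which makes the sialic acid Neu5Gc, fell from 614 ± 12.2 to 138 ± 5.79 CPM (-2.14, SE 0.12, edgeR adjusted p = 8.09e-05), and Arsb, a lysosomal sulfatase, fell with a log2 fold change of -2.44. Fkbp5 (ENSMUSG00000024222), a co-chaperone of steroid receptors, rose from 51.7 ± 20.7 to 1168 ± 478 CPM (4.50, SE 0.34, edgeR adjusted p = 0.000191). Zbtb16, a transcription factor induced by glucocorticoids, rose with a log2 fold change of 2.78 and the clock gene Per1 with 2.95. The rule also named St18 (3.63) and Tenm4 (3.56) among the higher genes, and Nppb (-2.66), Nrg1 (-2.58), Kctd16 (-2.50), Ighm (-1.89) and Spats2l (-1.87) among the lower ones.

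Over all 10771 genes tested in macrophage-like nuclei, 230 were higher and 219 lower in the HFpEF model by edgeR, and DESeq2 called 258. The total of 449 was 997 without the filter on low counts, 1019 at Leiden resolution 2.0, 289 in purer nuclei, 1221 with background-laden clusters included and 719 with the 10% mitochondrial limit. These nuclei numbered 573 to 1185 per library, with 1415477 to 2850703 UMIs. An estimated 20.2% to 35.4% of their UMIs were background, and the cardiomyocyte gene Myl2, a light chain of myosin, was itself lower in them (log2 fold change -0.83). In free-RNA-like nuclei, Fkbp5 went from 17.5 to 387 CPM, Zbtb16 from 227 to 2304, Nppb from 42.7 to 12.8 and Nrg1 from 74.9 to 32.8 (control to HFpEF model means), while Ms4a4a went from 1.5 to 37.3, Timd4 from 3.50 to 1.67 and Cmah from 23.7 to 22.5.

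**Figure D2:**
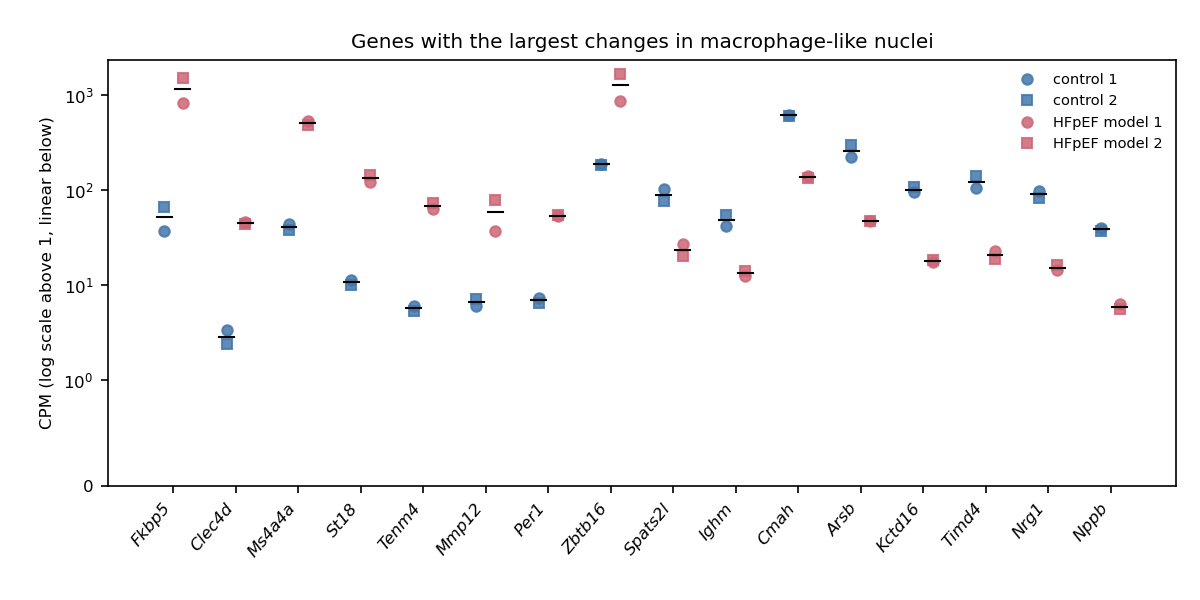
CPM (vertical axis, log scale above 1 and linear below) of 16 genes in macrophage-like nuclei (horizontal axis), 1 point per library. They are the 8 higher and 8 lower genes with the largest changes among those that meet the limits of the naming rule. Circles and squares are replicates 1 and 2, blue is control, red is the HFpEF model, and black bars are group means. Ms4a4a had group means of 41.4 and 514 CPM, and Timd4 of 123 and 20.9 CPM.

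Genes that mark resident macrophages went both ways in macrophage-like nuclei. Of 18 measured members, 2 rose and 2 fell (4 and 3 adjusted over the list alone): the scavenger receptors Cd163 (log2 fold change 1.22) and Stab1 (0.83) rose while Timd4 fell, and the other fall, Mgl2, was lost without HFpEF model 2 (edgeR adjusted p = 0.0556). The list's median was 0.14 against a mean of -0.04 (camera adjusted p = 0.955; 0.984 with an estimated correlation). Of 14 genes for receptors and complement that serve the uptake of dying cells, the kinase receptor Mertk (1.15) and Stab1 rose and Timd4 fell (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.979), with a median of 0.02 and a mean of -0.07. Of 14 genes of lipid-associated macrophages, Lgals3, a galactose-binding lectin, rose by 2.27 and Gpnmb, a lysosomal glycoprotein, by 3.40 on the log2 scale, and Fabp4 fell (the same numbers adjusted over the list alone), a call lost without control 2 (edgeR adjusted p = 0.0910) or HFpEF model 1 (0.126). That list was called higher (camera adjusted p = 0.0402), but not with an estimated correlation (adjusted p = 0.86) and not without control 1 (adjusted p = 0.0567) or HFpEF model 1 (0.576).

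All 15 measured cell cycle genes had negative values in macrophage-like nuclei, and 3 fell (6 adjusted over the list alone): the kinesin Cenpe (log2 fold change -1.54), the cytokinesis factor Ect2 (-1.46) and the formin Diaph3 (-0.85). The list was called lower (camera adjusted p = 1.21e-08, adjusted p = 0.86 with an estimated correlation). Each of the 3 calls was lost with some library left out, while the log2 fold changes stayed negative. Cenpe had -1.36 without control 2 (edgeR adjusted p = 0.0741). Ect2 had -1.25 without control 2 (0.219), -1.38 without HFpEF model 1 (0.158) and -1.51 without HFpEF model 2 (0.0610), and Diaph3 had -0.75 without control 1 (0.107) and -0.66 without HFpEF model 2 (0.151). Of 9 genes of antigen presentation by MHC class II, 7 had negative values, and the 1 call, the protease Ctss, rose (0.76; 1 higher and 3 lower adjusted over the list alone). The list was called lower (camera adjusted p = 0.0498, adjusted p = 0.984 with an estimated correlation), but not without control 1 (0.106), control 2 (0.0693) or HFpEF model 2 (0.141). Markers of fibroblasts were also lower as a list in these nuclei (11 negative values of 11, 1 lower adjusted over the list alone; camera adjusted p = 0.00983, adjusted p = 0.984 with an estimated correlation), which ended without control 1 (0.0583) or HFpEF model 2 (0.636). Lists of NF-kB and inflammasome cytokines (9 genes; camera adjusted p = 0.955) and of recruited monocyte genes (4 genes; 0.858) were not called.

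Clustered with all genes, most macrophage-like nuclei split by group: 1 subcluster held 88.1% and 87.7% of control nuclei of the class against 2.19% and 0.524%, and another 1.74% and 1.86% against 80.5% and 85.5%, each with 10 of its 10 leading genes called between the groups. An MHC class II high subcluster there held 4.11% and 5.17% against 15.1% and 11.9%. Clustered again without the called genes, these nuclei formed a resident group, 2 MHC class II high groups, a dividing group, an interferon group and an unnamed group. The unnamed group, 41 nuclei led by genes such as Tnni3k and Fgf1, held 3.48% and 0.398% of control nuclei of the class against 0.422% and 1.92%. Although left out of the clustering, called genes were 3 of the 10 leading genes of the resident group and 8 of 10 in the larger MHC class II high group. The resident group held 54.3% and 61.3% of control macrophage-like nuclei and 65.8% and 64.0% of HFpEF model ones, and the larger MHC class II high group 35.0% and 28.4% against 26.7% and 28.1%, the other direction from the clustering with all genes. Dividing nuclei made up 3.16% and 5.17% against 2.28% and 1.92% (each of these 3 with a two-sided exact permutation p of 0.333, the smallest possible). The smaller MHC class II high group held 3.48% and 4.24% against 4.39% and 3.66%, which overlap (two-sided exact permutation p = 0.667). Inside the resident group, 238 genes were higher and 208 lower by edgeR, and inside the larger MHC class II high group 182 and 197. Ms4a4a rose in both (log2 fold change 3.51 and 4.30), and Timd4 (-2.54 and -2.53) and Cmah (-2.08 and -2.63) fell in both. In the MHC class II high group Mmp12 rose by 4.75 and Lgals3 by 3.21 on the log2 scale, while Lgals3 in the resident group had a log2 fold change of 1.06 (edgeR adjusted p = 0.106). The difference between the groups was not tested. The interferon group was small, with 0.633% and 0.531% against 0.422% and 0.349%.

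Several targets of the glucocorticoid and mineralocorticoid receptors, the nuclear receptors for adrenal steroids, rose in every main class. Zbtb16 had log2 fold changes of 2.78 in macrophage-like, 3.70 in cardiomyocyte-like, 3.50 in fibroblast-like, 4.82 in vascular endothelial-like and 4.91 in pericyte-like nuclei, and Fkbp5 had 4.50, 4.74, 2.15, 3.71 and 2.75. Tsc22d3, a glucocorticoid-induced leucine zipper protein followed into cardiomyocyte-like nuclei after its values were seen, rose by 1.81, 0.79, 2.33, 2.17 and 1.37 on the log2 scale in the same order. Both Zbtb16 and Fkbp5 also passed in all 6 other classes tested. In Schwann-like nuclei their rises were 0.663 and 0.708 of their highest CPM in free-RNA-like nuclei, within the estimated background share of 51.4% to 71.8%. The rise of Zbtb16 in T or NK-like nuclei was 0.637 of that level, within a share of 47.8% to 74.2%. Background can therefore account for these rises. The number of targets that rose was 6 of 13 in macrophage-like nuclei (9 adjusted over the list alone; camera adjusted p = 1.03e-08, adjusted p = 0.86 with an estimated correlation), 10 of 14 in cardiomyocyte-like (11 over the list alone; 1.35e-07, 0.891 with an estimated correlation) and 13 of 14 in fibroblast-like nuclei (14 over the list alone; 9.36e-16, 0.301 with an estimated correlation). In vascular endothelial-like nuclei it was 12 of 14 (14 adjusted over the list alone; camera adjusted p = 4.34e-15, adjusted p = 0.398 with an estimated correlation), and in pericyte-like nuclei 10 of 12 (10 over the list alone; 3.63e-13, 0.673 with an estimated correlation, 0.0407 by fry).

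Genes of the circadian clock changed as well. Ciart outside cardiomyocyte-like nuclei, Per2 in cardiomyocyte-like, and Arntl in macrophage-like, cardiomyocyte-like and pericyte-like nuclei lie outside the rule for named genes and were chosen after their values were seen. The clock repressors Per1 and Per2 rose in cardiomyocyte-like (log2 fold change 2.20 and 1.34), fibroblast-like (2.05 and 1.95), vascular endothelial-like (2.59 and 2.52) and pericyte-like nuclei (2.21 and 2.12), and so did the repressor Ciart (2.98, 3.20, 2.35 and 2.76). Arntl, the activator that drives the Per genes, fell in the same 4 classes (-1.07, -1.14, -1.14 and -1.19). In macrophage-like nuclei Per1 rose, and Per2 (1.44, edgeR adjusted p = 0.0773) and Arntl (-0.22, 0.461) did not pass. As a list, clock genes were called higher in fibroblast-like nuclei (7 higher and 2 lower of 16; 9 and 3 adjusted over the list alone; camera adjusted p = 0.0150, adjusted p = 0.301 with an estimated correlation) and in vascular endothelial-like nuclei (8 and 1 of 16; 10 and 4 over the list alone; 0.00819, 0.398 with an estimated correlation). In pericyte-like nuclei the list was called higher too (5 and 2 of 15; 8 and 3 over the list alone; camera adjusted p = 0.0137, adjusted p = 0.789 with an estimated correlation), but not without control 1 (0.0598) or HFpEF model 1 (0.280). In cardiomyocyte-like nuclei 4 members rose and 3 fell of 16 (6 and 4 over the list alone; camera adjusted p = 0.583), and in macrophage-like nuclei 1 of 14 rose (2 over the list alone; 0.889), with a median of -0.08 and a mean of 0.21. The labels give no time of collection.

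**Figure D3:**
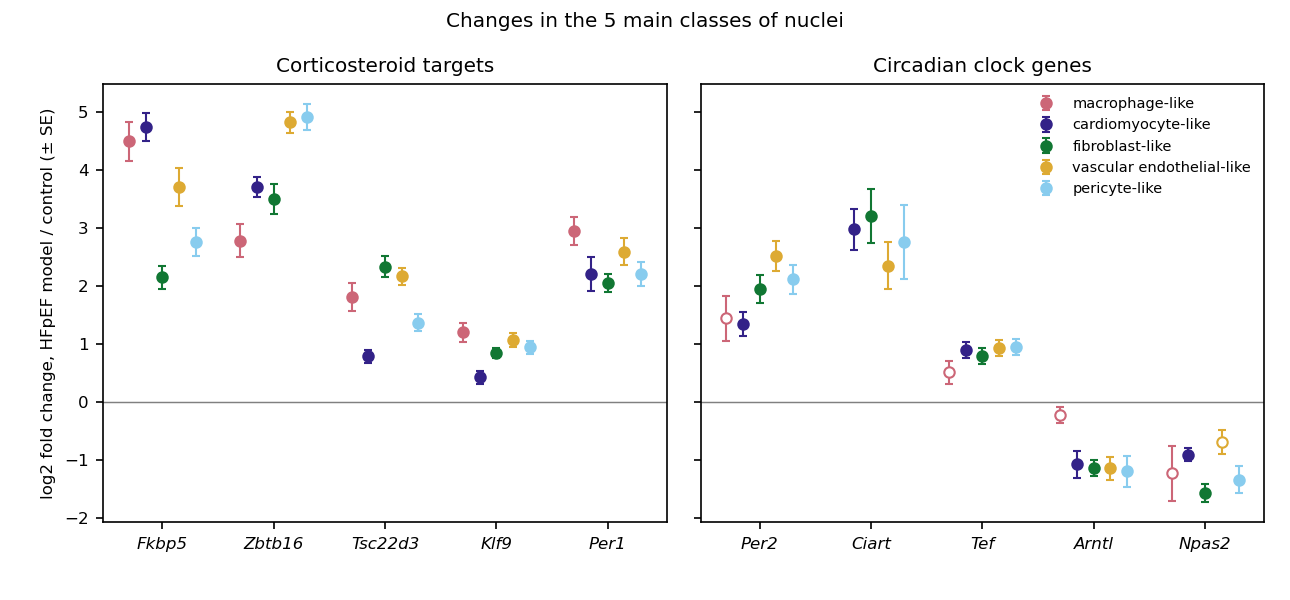
Log2 fold change of HFpEF model over control (vertical axis) for 5 corticosteroid targets (left) and 5 clock genes (right) in the 5 main classes of nuclei, as points with bars of 1 SE; filled points have an edgeR adjusted p under 0.05. Fkbp5 and Zbtb16 lie above 0 in each class, from 2.15 to 4.74 and from 2.78 to 4.91, and Arntl lies at -1.07 to -1.19 in every class except macrophage-like nuclei (-0.22).

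In cardiomyocyte-like nuclei, several genes of cardiac stress fell in the HFpEF model. The natriuretic peptide gene Nppb (log2 fold change -2.33), the stress-induced ankyrin protein gene Ankrd1 (-1.74) and skeletal actin Acta1 (-2.52) fell, and Fhl1, a LIM protein of the sarcomere, rose (1.31). Nppb, Ankrd1 and Acta1 were called lower in all 5 main classes. The classes share free RNA, so this does not show a fall made outside cardiomyocyte-like nuclei. Colq, which anchors acetylcholinesterase, fell from 76.1 ± 6.61 to 4.17 ± 0.202 CPM (SD, n = 2 per group, -4.16, SE 0.14, edgeR adjusted p = 3.76e-06), and Itgb6, an integrin chain, from 565 to 97.4 CPM (-2.51). The noncoding RNA Snhg11 rose from 1.54 ± 0.75 to 72.1 ± 20.1 CPM (5.60, SE 0.32, edgeR adjusted p = 1.81e-05), and Dpp6, a partner of potassium channels, with a log2 fold change of 4.64. The rule also named Slc35f3 (3.98), Ptgds (3.46), Csdc2 (2.84) and Rp1 (2.83) among the higher genes, and Frem2 (-2.80), Pdgfc (-2.64), Scin (-2.46), Sorcs2 (-2.45), Clstn2 (-2.38) and Slit2 (-2.24) among the lower ones. Slit2 lost its call without HFpEF model 1 (edgeR adjusted p = 0.0625).

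Of 13 cardiac stress and fetal genes in cardiomyocyte-like nuclei, 1 rose and 5 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.0304, adjusted p = 0.891 with an estimated correlation), and the list was not called without control 2 (0.0692) or HFpEF model 2 (0.216). Of 26 genes of fatty acid oxidation, the main fuel pathway of heart muscle, 3 rose and 8 fell (3 and 12 adjusted over the list alone, camera adjusted p = 0.0327, adjusted p = 0.891 with an estimated correlation): the fatty acid binding protein Fabp3 (log2 fold change -0.92) and the dehydrogenase Acadm (-0.78), both called lower in all 5 main classes, and the thioesterase Acot2 (-1.41) fell, while the regulator Ppara rose (0.85). That call ended without control 2 (0.106) or HFpEF model 1 (0.555). Of 19 interferon response genes, 1 rose and 7 fell (2 and 8 over the list alone; camera adjusted p = 0.00126, adjusted p = 0.891 with an estimated correlation), among them Ifit2 (-1.41) and Parp14 (-0.84). Of 18 genes of the unfolded protein response, the sensor Atf6 (1.23) and Herpud1 (1.78), which serves the breakdown of misfolded proteins, rose and 2 fell (3 and 3 over the list alone; camera adjusted p = 0.883; median -0.10, mean 0.06). The falls, Calr and Hspa5, were both lost without control 1 (edgeR adjusted p = 0.0584 and 0.114), control 2 (0.175 and 0.205) or HFpEF model 2 (0.0831 and 0.0995). Of 13 calcium handling genes 3 rose and 3 fell (the same over the list alone; 0.724), among them the calcium release channel Ryr2 (0.90) and the kinase Camk2d (-0.73). Of 16 sarcomere genes 1 rose and 4 fell (2 and 6 over the list alone, camera adjusted p = 0.583), among them Tcap (0.88) and Mybpc3 (-0.87, called lower in all 5 main classes). The falls of Nebl and Myom2 were lost without control 1 (edgeR adjusted p = 0.126 and 0.154) or control 2 (0.0576 and 0.283). Of 6 sex-linked genes, Eif2s3y rose (0.61) and Tsix fell (-1.35), with the same calls over the list alone (camera adjusted p = 0.583). Eif2s3y lost its call without control 1 (edgeR adjusted p = 0.0543) and Tsix without control 2 (0.195) or HFpEF model 1 (0.178).

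Over all 17613 genes tested in cardiomyocyte-like nuclei, 1337 were higher and 1924 lower by edgeR. The total of 3261 went to 1446 without control 1 and 1752 without control 2. Markers of endothelial cells were lower in these nuclei (10 of 12 fell, 10 adjusted over the list alone; camera adjusted p = 0.000856, adjusted p = 0.891 with an estimated correlation), among them the VEGF receptor Kdr (log2 fold change -1.39) and the junction protein Cdh5 (-1.04). Fibroblast markers were lower too (2 of 12 fell, 3 over the list alone; camera adjusted p = 0.0304, adjusted p = 0.891 with an estimated correlation), a call lost without control 1 (0.0502), control 2 (0.0684) or HFpEF model 2 (0.524). Their 2 falls were lost without control 1 (Col3a1, edgeR adjusted p = 0.147, and Abca8a, 0.251), Col3a1 also without control 2 (0.0746) and Abca8a without HFpEF model 2 (0.0552). Different clusters held most of this class in the 2 groups: cluster 0 held 31.2% and 33.7% of kept control nuclei against 0.849% and 0.380%, cluster 18 held 2.44% and 2.16% against 0.0336% and 0.0423%, and cluster 2 held 0.655% and 1.18% against 21.8% and 32.6%. Cluster 21 held 0.489% and 1.10% against 0.297% and 0.254%.

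In fibroblast-like nuclei, 7 of 17 genes of activated fibroblasts rose in the HFpEF model and 1 fell. Postn, a matrix protein of activated fibroblasts, rose from 19.2 ± 0.989 to 83.5 ± 10.6 CPM (SD, n = 2 per group, log2 fold change 2.12, SE 0.13, edgeR adjusted p = 0.000170). Tnc, a matrix protein of wound repair, rose by 2.74 on the log2 scale and the growth factor Ccn2 by 1.71. The protease Fap fell (-1.15). The list was called higher, but not with an estimated correlation (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.00e-06, adjusted p = 0.301 with an estimated correlation). Collagens and matrix genes went both ways: of 24 genes of collagens and matrix, 4 rose and 5 fell (5 and 6 over the list alone; camera adjusted p = 0.616), with the matrix protein Fbln2 higher (0.87) and Col15a1, a collagen of basement membranes, lower, from 769 ± 14.8 to 223 ± 80.0 CPM (-1.78, SE 0.19, edgeR adjusted p = 0.00158). The falls of Col3a1 and Col6a2 were lost without control 1 (edgeR adjusted p = 0.160 and 0.187), and that of Col6a2 without control 2 (0.124). Of 15 genes of the TGF-beta response 4 rose and 2 fell (9 and 3 over the list alone; camera adjusted p = 0.0173, adjusted p = 0.301 with an estimated correlation). That call ended without HFpEF model 1 (0.13) and with doublets kept (0.10), and 2 of the 4 rises, Bhlhe40 and Pmepa1, were lost without control 1 (edgeR adjusted p = 0.0892 and 0.202) or control 2 (0.114 and 0.172).

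The other genes named in fibroblast-like nuclei were Csmd1 (log2 fold change 2.66), Fmo2 (2.30), Adamtsl2 (2.10) and, from the inflammatory list, the complement gene C4b (2.04) among the higher. The lower ones were Grm8 (-3.16), Gna14 (-2.69), Tll2 (-2.24), Hunk (-2.07), Lepr, the leptin receptor (-1.85), Hs6st2 (-1.82) and Nrg1 (-1.77). The fall of Nrg1 was 0.348 of its highest CPM in free-RNA-like nuclei, close to the largest estimated share of background given below. Of 12 inflammatory genes, C4b alone passed (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.937; median -0.09, mean 0.14). Cell cycle genes were lower as a list (1 of 13 fell; 1 higher and 4 lower over the list alone; camera adjusted p = 0.00563, adjusted p = 0.301 with an estimated correlation), and their 1 call, Top2a (-1.76), was lost without control 1 (edgeR adjusted p = 0.273), control 2 (0.0896) or HFpEF model 2 (0.0519). Over all 14659 genes tested, 489 were higher and 506 lower by edgeR. The total of 995 was 208 without control 1, 382 without control 2 and 1992 without HFpEF model 1. Background made up an estimated 17.5% to 31.2% of UMIs in these nuclei, in which the cardiomyocyte gene Myl2 was lower (-0.75) and Ryr2 higher (1.18, not called without control 1, edgeR adjusted p = 0.0524, or control 2, 0.115).

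In vascular endothelial-like nuclei, 6 of 13 angiogenic and tip cell genes fell in the HFpEF model and 1 rose. The apelin receptor Aplnr (log2 fold change -1.65) and the basement membrane collagens Col4a1 (-0.81) and Col4a2 (-0.73) fell, whereas Flt1, a VEGF receptor that also acts as a decoy, rose (1.07). Without control 2, Col4a1 (edgeR adjusted p = 0.0590) and Col4a2 (0.0726) were not called. The list was called lower, but not with an estimated correlation (1 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.000106, adjusted p = 0.398 with an estimated correlation). Of 13 genes of nitric oxide and vessel tone 3 rose (4 higher and 1 lower over the list alone; camera adjusted p = 0.0440, adjusted p = 0.398 with an estimated correlation), among them the flow-induced transcription factors Klf4 (0.93) and Klf2 (0.93). That list was not called without control 1 (0.0879), HFpEF model 1 (0.314) or with the 10% mitochondrial limit (0.0762), and Klf2 was not called without control 2 (edgeR adjusted p = 0.0740), nor Nostrin without control 1 (0.135) or control 2 (0.227). Of 10 genes of fatty acid transport by capillaries 4 rose and 1 fell (5 and 2 over the list alone; camera adjusted p = 0.339). Of these calls Gpihbp1, Pparg and Meox2 were lost without control 1 (edgeR adjusted p = 0.153, 0.191 and 0.124) or control 2 (0.0850, 0.263 and 0.198), Rgcc without control 2 (0.0818) and Pparg without HFpEF model 2 (0.0822). Of 9 genes of adhesion and inflammation 2 rose and 1 fell (the same over the list alone; 0.952; median -0.11, mean 0.13), among them Nfkbia, an inhibitor of NF-kB (0.99). The rise of Sele was lost without control 1 (edgeR adjusted p = 0.168) or control 2 (0.152). The fall of Cxcl9 was lost without control 1 (0.164), control 2 (0.289), HFpEF model 1 (0.0643) or HFpEF model 2 (0.0928).

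Stc1, a secreted glycoprotein hormone, rose from 3.26 ± 0.235 to 39.5 ± 2.05 CPM in vascular endothelial-like nuclei (SD, n = 2 per group, log2 fold change 3.61, SE 0.24, edgeR adjusted p = 1.70e-06), and the cyclin Ccnd3 from 75 ± 6.93 to 502 ± 51.9 CPM (2.76, SE 0.13, edgeR adjusted p = 5.97e-08). Spock2 (3.19) and Slc10a6 (2.94) rose too. Cd247 (-2.59), Nppb (-2.34), Nr5a2 (-2.16), the receptor kinase Kit (-2.09), Col15a1 (-2.03), Apol10b (-1.89) and the guidance receptor Robo2 (-1.81) fell. Egr1, an immediate early gene, fell by 2.41 on the log2 scale (edgeR adjusted p = 0.0178), and without control 2 its value was -1.15 and not called (0.283). Cell cycle genes were lower as a list (1 of 8 fell; 3 adjusted over the list alone; camera adjusted p = 0.00215, adjusted p = 0.398 with an estimated correlation). Their 1 call, Diaph3 (-1.89), was lost without control 2 (edgeR adjusted p = 0.104). Over all 12415 genes tested, 572 were higher and 543 lower by edgeR. The total of 1115 was 503 without control 1 and 239 without control 2, and DESeq2 called 651. Background made up an estimated 25.6% to 37.0% of UMIs, and Myl2 was lower in these nuclei (-0.81, not called without control 2, edgeR adjusted p = 0.09) and Ryr2 higher (0.95, not called without control 2, 0.143). Fibroblast markers were lower as a list (1 of 11 fell, 2 over the list alone; camera adjusted p = 0.0440, adjusted p = 0.732 with an estimated correlation), a call that ended without control 2 (0.164) or HFpEF model 2 (0.740). The 1 fall, Abca8a, was lost without control 1 (edgeR adjusted p = 0.188) or control 2 (0.206).

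In pericyte-like nuclei, the alkaline ceramidase Acer2 rose from 56.5 ± 9.53 to 267 ± 98.0 CPM (SD, n = 2 per group, log2 fold change 2.24, SE 0.22, edgeR adjusted p = 0.000113) and Carmil1, a regulator of actin capping, from 164 ± 3.18 to 633 ± 72.1 CPM (1.95, SE 0.12, edgeR adjusted p = 3.94e-06). The contractile kinase Mylk rose (0.62), the 1 call among 8 contractile genes (1 over the list alone; camera adjusted p = 0.306). It was not called without control 2 (edgeR adjusted p = 0.0631). Adcyap1r1, a neuropeptide receptor, fell from 45.0 to 10.7 CPM (-2.05). The rule also named Ctnnal1 (2.37) and Ces1d (2.07) as higher, whose rises were 0.280 and 0.285 of their highest CPM in free-RNA-like nuclei, within the share of background in these nuclei. The lower ones were Col15a1 (-1.90), Nrg1 (-1.67), Megf6 (-1.57), Dapk2 (-1.45), Prkg2 (-1.37) and the clock gene Npas2 (-1.34). The fall of Nrg1 was 0.395 of its highest CPM in free-RNA-like nuclei, close to the largest estimated share of background given below. Prkg2 lost its call without control 1 (edgeR adjusted p = 0.0746) or HFpEF model 2 (0.111). Over all 11186 genes tested, 329 were higher and 271 lower by edgeR, and DESeq2 called 297. The total of 600 was 376 without control 1, 369 without control 2 and 1196 without HFpEF model 1. Background made up an estimated 19.4% to 34.4% of UMIs, and the cardiomyocyte genes Myl2 (-0.65) and Ryr2 (1.20) changed in these nuclei.

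Of the 13 protein genes encoded by mitochondrial DNA, 13 were lower in each main class, as in the median share of mitochondrial UMIs of whole libraries. Their median log2 fold change was -1.24 in macrophage-like, -1.43 in cardiomyocyte-like, -1.19 in fibroblast-like, -1.10 in vascular endothelial-like and -1.16 in pericyte-like nuclei. The 5% limit acts on these same transcripts. With a limit of 10%, added after the data were seen, the medians were -1.39, -1.36, -1.38, -1.22 and -1.21.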

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

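The tests of a difference between 2 classes of nuclei were chosen after the changes within each class had been seen. The genes below were picked because edgeR called them in opposite directions in a pair of classes. Every gene so picked also passed the edgeR interaction test with the library as a block, so that test adds no support of its own, and only the differences it estimated are given. Hunk, a protein kinase gene, had a log2 fold change of 1.28 in macrophage-like and -2.07 in fibroblast-like nuclei, a difference of -3.36. Kctd16, an auxiliary subunit of GABA-B receptors, had -2.50 in macrophage-like and 0.73 in fibroblast-like nuclei, a difference of 3.27. Cmah, which makes a sialic acid, had -2.14 in macrophage-like and 0.86 in vascular endothelial-like nuclei, a difference of 2.99. Nostrin, which binds endothelial nitric oxide synthase, had 0.53 in vascular endothelial-like and -0.61 in pericyte-like nuclei, a difference of -1.12; without control 1 or control 2 its edgeR adjusted p in vascular endothelial-like nuclei was 0.135 or 0.227 (log2 fold change 0.54 or 0.51). Bicc1, an RNA-binding protein gene, had -0.54 in fibroblast-like and 0.47 in pericyte-like nuclei, a difference of 1.01; its edgeR adjusted p in pericyte-like nuclei was 0.25 without control 1 (log2 fold change 0.43) and 0.133 without control 2 (0.51). Pparg, a regulator of lipid storage, had -0.37 in cardiomyocyte-like and 0.64 in vascular endothelial-like nuclei, a difference of 0.98; its edgeR adjusted p in vascular endothelial-like nuclei was 0.191 without control 1 (log2 fold change 0.59), 0.263 without control 2 (0.69) and 0.0822 without HFpEF model 2 (0.32).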

How the results depend on the processing

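The 10% mitochondrial limit, the background-laden clusters included, the free RNA profile subtracted and the shares of named nuclei were chosen after the data were seen; for every change below, the cause was not tested unless said. Of 231 genes named in the main classes, 104 kept their direction and call in every setting run, and of 3501 values over settings 3096 kept both, 391 lost the call and 14 turned. With counts of 449 (macrophage-like), 3261 (cardiomyocyte-like), 995 (fibroblast-like), 1115 (vascular endothelial-like) and 600 genes (pericyte-like), DESeq2 called 258 in macrophage-like, 651 in vascular endothelial-like and 297 in pericyte-like nuclei. Without the filter on low counts edgeR called 997 in macrophage-like, 2054 in cardiomyocyte-like, 1976 in fibroblast-like and 929 in pericyte-like nuclei. Purer nuclei, which are fewer, gave 289 in macrophage-like, 525 in fibroblast-like, 368 in vascular endothelial-like and 197 in pericyte-like nuclei. Leiden resolution 2.0 gave 1019 and the 10% limit 719 in macrophage-like nuclei, and doublets kept gave 1493 in fibroblast-like nuclei. Background-laden clusters included gave 1221 in macrophage-like and 1000 in pericyte-like nuclei, and the free RNA profile subtracted gave 485 in vascular endothelial-like and 260 in pericyte-like nuclei.

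The stricter filter on nuclei (at least 1000 UMIs and 800 genes, at most 1% mitochondrial UMIs) left 1 to 733 fibroblast-like and 2 to 89 vascular endothelial-like nuclei per library and called 255 and 120 genes; with so few nuclei its values are of little weight. It was not run for macrophage-like and pericyte-like nuclei, of which some libraries kept 0. Under it Postn (-0.99), Hunk (0.60), Hs6st2 (7.14), Col3a1 (0.24), Col6a2 (1.11), Fap (0.60), Ryr2 (-1.15), Kdr (7.92), Cdh5 (7.86) and Tek (0.31) turned in fibroblast-like nuclei, and Robo2 (1.57), Nfkbia (-0.61), Ryr2 (-0.82) and Abca8a (0.54) in vascular endothelial-like nuclei. The log2 ratio of shares under it was 5.44 for macrophage-like nuclei (edgeR adjusted p = 4.84e-07), and turned to 6.61 for fibroblast-like, 3.40 for vascular endothelial-like, 1.70 for lymphatic endothelial-like, 6.20 for pericyte-like, 2.24 for smooth muscle-like, -0.95 for T or NK-like and 1.84 for epicardial-like nuclei. Other shares turned with purer nuclei (cardiomyocyte-like 0.13, endocardial-like -1.35, lymphatic endothelial-like 1.18), the 10% limit (cardiomyocyte-like 0.28, fibroblast-like 0.011, lymphatic endothelial-like 0.11, T or NK-like -0.61), shares of named nuclei (fibroblast-like 0.12, lymphatic endothelial-like 0.18, epicardial-like 0.12) and doublets kept (T or NK-like -0.12).

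Leaving out each library in turn, where the lone library is assumed to vary like the other group, gave 336 to 433 genes in macrophage-like, 1446 to 3370 in cardiomyocyte-like, 208 to 1992 in fibroblast-like, 239 to 1550 in vascular endothelial-like, 369 to 1196 in pericyte-like, 97 to 947 in endocardial-like, 0 to 308 in lymphatic endothelial-like, 16 to 382 in smooth muscle-like, 146 to 271 in epicardial-like, 26 to 213 in T or NK-like and 35 to 156 in Schwann-like nuclei. The log2 ratio of shares of macrophage-like nuclei ranged from -0.12 (without HFpEF model 1) to 0.59. Those of endocardial-like nuclei ranged from -0.18 (without HFpEF model 1) to 0.76, of lymphatic endothelial-like from -0.35 to 0.091 (without HFpEF model 2), of T or NK-like from -0.33 (without control 1, and -0.11 without HFpEF model 1) to 0.46 and of epicardial-like from -0.75 to 0.73 (without control 2). Gene lists past the threshold numbered 5, 6, 5, 6 and 2 in macrophage-like, cardiomyocyte-like, fibroblast-like, vascular endothelial-like and pericyte-like nuclei, and 2 to 5, 3 to 5, 4 to 7, 5 to 6 and 1 to 2 with 1 library left out. Camera with estimated correlation called 0 in each of these classes (unadjusted 0, 0, 1, 0 and 0), and fry called 0 in the first 4 (unadjusted 4, 4, 5 and 3) and 2 in pericyte-like nuclei (corticosteroid targets, adjusted p = 0.0407, and sex-linked genes, 0.00351). Pericyte-like nuclei had 5 lists with the free RNA profile subtracted. Of the called lists, 2 of 7 lost their call with background-laden clusters included and 1 of 18 with the free RNA profile subtracted. With doublets kept 2 of 24 lost it, and with the 10% limit 2 of 24.

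The groups share the replicate numbers 1 and 2, and the labels do not say whether these mark a batch, so no pairing was used. Same-numbered deviations had correlations of -0.13 to -0.02 in the main classes, which cannot exclude a shared batch. With the replicate block, calls went to 321 in macrophage-like, 4049 in cardiomyocyte-like, 1132 in fibroblast-like, 925 in vascular endothelial-like, 241 in pericyte-like, 870 in endocardial-like, 261 in lymphatic endothelial-like, 175 in smooth muscle-like, 340 in epicardial-like, 63 in T or NK-like and 142 in Schwann-like nuclei. The share of MHC class II high macrophages was 8.84 percentage points higher in the HFpEF model as first clustered, -19.7 at resolution 1.0 and -4.13 when clustered without called genes, and dividing nuclei went from -3.51 to -2.07 points.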

Other observations

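The time-of-day test and the test of the 5% mitochondrial limit were chosen only after the results they bear on were seen, and so were the comparisons across classes. Endocardial-like nuclei, from the lining of the chambers, had less Nrg1, a growth factor for cardiomyocytes, with 5182 ± 1792 against 1143 ± 692 CPM (SD, n = 2 per group, log2 fold change -2.17, SE 0.38, edgeR adjusted p = 0.0115). The immediate early gene Nr4a1 (-3.48, edgeR adjusted p = 0.0496), Hs3st4 (-2.76) and the calcium channel subunit Cacnb4 (-2.38) fell as well, and Spock2 (3.13) and Tsc22d3 (2.58) rose. At Leiden resolution 2.0, 1 endocardial-like cluster was led by Nrg1. It held 449 and 1002 control nuclei against 231 and 110 HFpEF model nuclei, doublets included. Another, led by Vwf, held 337 and 273 against 2030 and 780. Whether Nrg1 fell within such clusters or through their mix was not tested. Lymphatic endothelial-like nuclei had less Cxcl12, a chemokine (-1.75), Nlgn1 (-1.84) and Ncam1 (-1.66), and more Tes (1.93) and Slc10a6 (1.71). In smooth muscle-like nuclei Samd5 (-2.31), the clock gene Npas2 (-2.27) and Robo2 (-2.21) fell, and Ptgds, a prostaglandin synthase, rose (2.93), by 0.574 of its highest CPM in free-RNA-like nuclei. Epicardial-like nuclei had less Nxph1 (-3.14), Pclo (-2.82), Ppfia2 (-2.11) and Sh3gl2 (-1.89), and more Adam22 (2.60), whose rise was 0.357 of its highest CPM in free-RNA-like nuclei, close to the largest estimated share of background in these nuclei. In Schwann-like nuclei the lipid carrier Apod rose from 16.4 ± 3.81 to 319 ± 43.8 CPM (SD, n = 2 per group, log2 fold change 4.28, SE 0.42, edgeR adjusted p = 8.19e-21). The p-values in this class are nearly normal tails of the fold change over its SE. They therefore rest on a spread pooled over genes, not on each gene's own spread between libraries. Cfap61 rose too (2.89), while Lsmem1 (-3.50), Vcan (-3.42), B3galt1 (-3.30) and Cdh20 (-3.18) fell. The changes of Cfap61 and Lsmem1 were 0.669 and 0.560 of their highest CPM in free-RNA-like nuclei, within the range of background given below. The genes the rule named in T or NK-like nuclei included markers of other cells, such as Vwf of endothelium (4.06) and Itgb6, abundant in cardiomyocyte-like nuclei (-3.26), beside Mcf2l (3.13), Fmo2 (2.75), Lsmem1 (-2.65), Zfp608 (-2.08) and Ppp1r14c (-2.06). Apart from Vwf their changes were 0.419 to 0.697 of the highest CPM in free-RNA-like nuclei, and background made up an estimated 47.8% to 74.2% of their UMIs, and 51.4% to 71.8% in Schwann-like, 28.1% to 48.5% in smooth muscle-like, 21.8% to 34.1% in epicardial-like, 18.7% to 36.8% in endocardial-like and 21.0% to 34.1% in lymphatic endothelial-like nuclei.

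By edgeR, 407 genes were higher and 336 lower in endocardial-like nuclei, 150 and 95 in lymphatic endothelial-like, 85 and 42 in smooth muscle-like, 104 and 65 in epicardial-like, 100 and 58 in Schwann-like and 16 and 10 in T or NK-like nuclei. The endocardial-like total of 743 was 97 without control 2. The lymphatic endothelial-like total of 245 was 0 by edgeR without control 1 (681 unadjusted, 24 by DESeq2) and without control 2 (766 unadjusted, 14 by DESeq2), and 96 without HFpEF model 2. The smooth muscle-like total of 127 was 16 without control 1, 74 without control 2, 382 without HFpEF model 1 and 194 without HFpEF model 2. The epicardial-like total of 169 was 271 without HFpEF model 1. The Schwann-like total of 158 was 40 without control 1, 35 without control 2 and 91 without HFpEF model 2, and the T or NK-like total of 26 was 129 without HFpEF model 1 and 213 without HFpEF model 2. Across the 5 main classes, 50 genes were higher and 59 lower in all 5 of 9956 tested in each, of which 13 of the lower were mitochondrially encoded; independent lists of these sizes would share 0.000769 and 0.000930. Picked out after their values were seen, Snhg11 (log2 fold change 5.43 in macrophage-like to 6.85 in vascular endothelial-like nuclei, folds that are uncertain in size since its control means were 0.143 to 1.54 CPM), Ccnd3 (1.74 in pericyte-like to 2.76 in vascular endothelial-like) and Rp1 (2.44 in vascular endothelial-like to 2.95 in pericyte-like) were higher in each, and Itgb6 (-2.81 in macrophage-like to -2.04 in fibroblast-like and vascular endothelial-like) and Col15a1 (-2.03 in vascular endothelial-like to -1.50 in macrophage-like) were lower in each. The classes share libraries and free RNA, so this overlap does not show a change made in each class. In contrast, 92 genes were called in opposite directions in at least 1 pair of these classes.

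Some corticosteroid targets rose in each of the 5 main classes (6 of 13 in macrophage-like nuclei). With an estimated correlation the list was called in none, but that setting called no list at all in these classes. Free RNA and the time of collection were tested as causes. The rise in CPM of the 41 called targets outside cardiomyocyte-like nuclei was a median of 0.762 of their CPM in free-RNA-like nuclei (quartiles 0.530 and 1.20). The bound set in advance against free RNA, a ratio above 1, was not reached; the reading against it as the whole cause rests on criteria added later, the lower quartile above 0.4 and the 33 of 41 targets still past the threshold after the free RNA profile was subtracted. Of 31 calls of clock genes with an assigned phase (Cry1 and Cry2, called in vascular endothelial-like nuclei, had none, and only Per1 was called in macrophage-like nuclei), 31 followed the known opposite phases (100%, 8 lower on the Arntl side and 23 higher on the Per side), as tissue taken at another time of day could show. These calls repeat the same genes over classes that share libraries and free RNA, so they are not separate agreements. Per1 is itself a listed corticosteroid target. Uncalled values went the other way for Per3 (-0.21), Dbp (-0.15) and Nr1d1 (-0.24) in macrophage-like, Nr1d1 (-0.33) in cardiomyocyte-like and Nfil3 (0.30) in fibroblast-like nuclei. A steroid response to stress or to the treatment that makes the model stays open, since the labels give neither the time nor the treatment.

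Mitochondrially encoded transcripts were lower in all 5 main classes, and the 5% limit and the amount of cytoplasmic RNA were tested as causes. Over all deposited barcodes, before any limit, the lower control median of mitochondrial UMIs lay 1.79 percentage points above the higher HFpEF model median, and with a 10% limit the 13 genes lay as far from 0 or farther in 4 of the 5 classes, which argues against the limit as the cause. This test first asked for all 5 classes and was rewritten after it came out as 4. Genes of the shortest span had a median more than 0.1 below those of the longest span in 0 of 5 classes (differences -0.05 to 0.03), so less cytoplasmic RNA around HFpEF model nuclei was not shown by these medians, but the bound set against it was not reached either. Called genes of the shortest span, which the test did not use, were more often lower than higher in each class. The lower and higher numbers were 48 and 22 (macrophage-like), 333 and 240 (cardiomyocyte-like), 102 and 53 (fibroblast-like), 100 and 79 (vascular endothelial-like) and 57 and 31 (pericyte-like). For the longest span they were 96 and 103, 836 and 450, 232 and 200, 250 and 239, and 132 and 159. Less cytoplasmic RNA, which may come from the isolation of the nuclei, and a change in mitochondrial transcription cannot be told apart here.

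The genes changed in macrophage-like nuclei were set against a change in the mix of macrophage states and against free RNA. Of the 449 called genes, 413 were tested inside the resident group, clustered without the changed genes. There the log2 fold changes were a median of 1.02 times those over all macrophage-like nuclei (quartiles 0.905 and 1.14), with 413 of 413 in the same direction. For these genes this argues against a change in the mix of states told apart by other genes as the whole cause. Mmp12, Tenm4 and Gpnmb were not tested in the resident group, so this does not cover them. Inside the larger MHC class II high group their log2 fold changes were 4.75, 4.95 and 3.34. States told apart by the changed genes themselves could not separate in that clustering, so a change in their mix stays open. The absolute change in CPM was a median of 0.869 of the highest CPM in free-RNA-like nuclei, above 1 for 209 of 449 genes and at or under 0.4 for 134. Free RNA therefore stays open for the set. For Nppb and Nrg1 the ratios were 0.761 and 0.708, above the estimated background share of 20.2% to 35.4%, but free RNA stays open for both. Nppb fell alike in macrophage-like and cardiomyocyte-like nuclei (log2 fold change -2.66 and -2.33). Nrg1 also fell in endocardial-like nuclei, where its level was far higher (5182 to 1143 CPM). Free RNA is an unlikely source for Ms4a4a, Timd4 and Cmah, whose changes in CPM were 11.4, 25.5 and 19.4 times their highest level in free-RNA-like nuclei.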
